A study of Homo sapiens with 23 samples.

How the data were processed

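The series holds RNA sequencing of CAL51 and MDA-MB-231 cells after 12 h with DMSO, 1 µM gefitinib, 200 nM THZ531 or both drugs. Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.32, aligned to GRCh38 (hg38) with STAR 2.4.1a and quantified with RSEM 1.2.25, and DESeq2 1.22.0 in R 3.5.1 was named for the authors' differential tests. The values deposited by the authors were RSEM TPM rounded to 2 decimals, in 1 table per line, for 60483 genes and 92 ERCC spike-ins. Symbols, coordinates and spans came from GENCODE v29 on GRCh38, where 56321 identifiers matched a symbol. TPM keep no read depth, so the depth per library and its counting error are unknown.

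The test planned before the data were examined was a negative binomial test on expected counts, with limma on log2(TPM + 1) as the stated fallback for files that hold TPM only, and the fallback was used. TPM were rescaled by an unweighted TMM (30% of log ratios and 5% of levels trimmed, genes with a mean TPM of at least 1), since the deposited TPM of each library sum to a fixed total. Genes with scaled TPM of at least 0.5 in at least 2 CAL51 or 3 MDA-MB-231 libraries were tested, with a pseudocount of 1. Each line was fitted with a mean per treatment over all of its libraries (limma 3.58.1 in R 4.3.3, empirical Bayes with a trend, two-sided), and genes with Benjamini-Hochberg adjusted p under 0.05 were called. The comparisons were each treatment against DMSO, the combination against THZ531 and against gefitinib, and the interaction of the drugs. Differences between the lines were planned only for expected counts and were not tested.

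The gene lists, 25 in number and written before the data were examined, covered ERK pathway output, ERBB receptors and ligands, FOXO-linked and PI3K feedback, CDK12/13 and transcription elongation, DNA damage repair, MYC targets, MYC stability regulators, translation initiation, cytosolic ribosomal proteins, mitochondrially encoded mRNAs, G1/S, G2/M, histones, p53, ATF4, NF-kB, interferon, apoptosis, YAP/TAZ, cholesterol synthesis, immediate-early mRNAs, and luminal, fibroblast, endothelial and leukocyte markers. They were tested with limma camera (correlation 0.01, Benjamini-Hochberg over lists and comparisons of a line), with an estimated correlation and fry as checks. Genes to name were set by a rule fixed in advance (drug targets, the highest and lowest changes, and the strongest members of lists), with a mean TPM of at least 5 (CPM in the plan). The rule returned 977 entries over all comparisons, and the report names a subset of them, with a few more protein-coding genes such as RGS16 and KRT17, chosen after the values were seen. Alternatives for single genes were run for that subset only. The endogenous to spike-in ratio was compared by exact two-sided permutation.

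The procedure was tested on simulated data with known changes in 100 genes per size or slightly fewer after filtering. Far more genes passed under THZ531 (11755 in CAL51, 12828 in MDA-MB-231), so the simulation does not judge scaling there. A log2 change of 1 was recovered in 50 to 100.0% of genes and a change of 2 in 96 to 100.0%, with 7 to 15 unchanged genes called per comparison. Alternatives set in advance were median-of-ratios factors (computed on TPM and tested with limma, not edgeR), TPM as deposited, scaling by summed spike-ins, no filter and a stricter filter, only the groups compared, a log2 change above 1, replicate number as a block, and leaving out each library. Added after the values were seen were pseudocounts of 0.1 and 0.5, library weights, spike-in scaling adjusted for the mixes (the spike-in scaling given in the report), protein-coding genes only, and leaving out the rRNA-rich libraries (rRNA above 5% of TPM), also with TPM as deposited. The adjustment for the mixes used the nominal ratios between them only. DESeq2 and edgeR, which need counts, were not run. No deposited library was left out of the main tests.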

Results

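RNA sequencing was done on CAL51 and MDA-MB-231, 2 established triple-negative breast carcinoma lines, both grown from pleural effusions. Each line was exposed for 12 h to the vehicle DMSO, to 1 µM gefitinib, an inhibitor of the EGFR tyrosine kinase, to 200 nM THZ531, a covalent inhibitor of the transcriptional kinases CDK12 and CDK13, or to both drugs together (the combination). The 23 libraries formed 8 groups of 3, except that gefitinib in CAL51 had 2 libraries (replicates 1 and 3). Cell numbers were equalized before lysis, ERCC spike-in RNAs were added after lysis, and stranded libraries of polyadenylated RNA were made from equal amounts of total RNA. The deposited TPM keep no read depth, so no counting interval is given. Nothing in the labels states that the replicates were separate cultures, so the p-values measure the spread between these libraries, which may be technical.

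Composition differed between groups before any gene was tested. In CAL51, the 13 mitochondrially encoded mRNAs and the mitochondrial rRNA and tRNA genes together held 18.4% ± 2.11 (SD, n = 3) of TPM with DMSO, 16% ± 0.691 (SD, n = 2) with gefitinib, 26.6% ± 0.892 (SD, n = 3) with THZ531 and 22.7% ± 2.24 (SD, n = 3) with the combination. The same share in MDA-MB-231 was 18.1% ± 4.26, 17.6% ± 7.64, 24.9% ± 0.979 and 31% ± 2.31 (SD, n = 3 each). Spliceosomal and other small nuclear RNA genes held 0.0442% ± 0.0349 of TPM with DMSO and 0.366% ± 0.0482 with THZ531 in CAL51, and 0.273% ± 0.437 and 0.399% ± 0.0372 in MDA-MB-231 (SD, n = 3 each), where DMSO replicate 1 alone held 0.778%. Ribosomal RNA genes held 32.1% of TPM in MDA-MB-231 DMSO replicate 1, 44.6% in MDA-MB-231 gefitinib replicate 3 and 16.9% in CAL51 gefitinib replicate 3, and at most 3.19% in the other 20 libraries. These 3 libraries are called rRNA-rich.

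The spike-ins gave a measure of RNA yield from equal numbers of cells. The log2 ratio of summed endogenous to summed spike-in TPM in CAL51 was 9.06 ± 0.33 with DMSO, 9.41 ± 0.14 with gefitinib, 8.50 ± 0.24 with THZ531 and 8.59 ± 0.57 with the combination (SD, n = 3, 2, 3 and 3). The differences from DMSO were 0.35, -0.56 and -0.46, with two-sided exact permutation p = 0.3, 0.2 and 0.3. In MDA-MB-231 the ratio was 10.18 ± 0.47 with DMSO, and differed by 0.20 with gefitinib, -0.61 with THZ531 and -0.77 with the combination (n = 3 each, two-sided exact permutation p = 0.8, 0.2 and 0.1). None of the 6 differences passed, and 3 libraries against 3 cannot give an exact p below 0.1. The labels do not say which of the 2 spike-in mixes a library received, so this was read from the ratios of the spike-ins themselves, and both CAL51 gefitinib libraries had the same mix. The adjustment removed only the nominal ratios between mixes. Spike-ins with a nominal ratio of 1 stood 0.44 to 0.64 higher (log2) in mix 1. An offset between mixes therefore stayed in the spike-in scaling, and CAL51 gefitinib cannot be separated from it. With spike-ins adjusted for the mixes and endogenous RNA scaled by TMM, the THZ531 and combination differences were -1.29 and -1.14 in CAL51 and -1.30 and -1.53 in MDA-MB-231.

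Scaling set the balance of higher and lower genes. Under THZ531 the median log2 change of all tested genes was 0.12 in CAL51 and 0.13 in MDA-MB-231 with TMM scaling, -0.41 and -0.44 with TPM as deposited, and -0.79 and -0.82 with spike-in scaling adjusted for the mixes, an alternative chosen after the values were seen. Under the combination the medians were 0.14 and 0.17, -0.44 and -0.54, and -0.68 and -0.95. Fold changes are on the log2(TPM + 1) scale after TMM scaling unless another scaling is named, are followed by ± 1 SE from limma, and understate the change of low genes. TPM given for single genes are TMM-scaled, as mean ± SD. For every single gene given by name as risen or fallen in a comparison of 2 groups, all libraries of the treated group lay beyond all libraries of its reference, which chance gives for 10% of genes with 3 libraries against 3 and 20% with 2 against 3.

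Gefitinib against DMSO asked what blocking EGFR alone does. CYP1A1, a cytochrome P450 enzyme induced through the aryl hydrocarbon receptor (ENSG00000140465.12, chromosome 15, 74719542 to 74725610, minus strand), rose in CAL51 from 12.8 ± 0.64 to 46.1 ± 1.74 TPM (SD, n = 3 and 2), a log2 change of 1.77 ± 0.10 (limma, Benjamini-Hochberg adjusted p = 1.1e-04). PHLDA1-AS1, an antisense transcript within PHLDA1 on the opposite strand, rose by 2.13 ± 0.23 (limma, Benjamini-Hochberg adjusted p = 0.0226). The labels do not say whether the counting used strand, so reads of PHLDA1 and its antisense partner may not be separated. EGFR itself, the receptor kinase that gefitinib inhibits, had a log2 change of 0.06 ± 0.13 in CAL51 and -0.03 ± 0.16 in MDA-MB-231, and MYC, the transcription factor, 0.47 ± 0.12 and 0.02 ± 0.11. Neither passed (limma, Benjamini-Hochberg adjusted p = 1, 1, 1 and 1). CDK12 (0.01 ± 0.16 and -0.15 ± 0.09), CDK13 (-0.17 ± 0.20 and -0.12 ± 0.12) and their cyclin CCNK (-0.01 ± 0.20 and 0.13 ± 0.10) did not pass either.

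These were the 2 genes that passed in CAL51 among 19797, both higher, while 377 had an unadjusted p under 0.05. In MDA-MB-231 0 of 17181 genes passed by limma, 465 had an unadjusted p under 0.05, and 3 passed with TPM as deposited, 9 under spike-in scaling and 6 with a pseudocount of 0.1. Targets of ATF4, the transcription factor of the integrated stress response, stood above other genes in CAL51: 0 of 24 passed over all genes, 8 passed when adjusted over the list alone, and the list median was 0.20 (limma camera, Benjamini-Hochberg adjusted p = 1.5e-18, and adjusted p = 0.0025 with an estimated correlation). YAP/TAZ targets in CAL51 had a median of 0.07, with 0 of 23 passing and 3 when adjusted over the list alone (limma camera, Benjamini-Hochberg adjusted p = 2.3e-05, and adjusted p = 0.0411 with an estimated correlation). For both lists no member passed in TPM as deposited or under spike-in scaling. The ERK pathway output list, which holds DUSP6 and SPRY4, had 0 of 21 members passing in CAL51 and 0 of 22 in MDA-MB-231, with medians of 0.04 and -0.03, and 1 and 0 passing when adjusted over the list alone. The ERBB receptor and ligand list had medians of 0.02 and -0.02 and 0 members passing in both lines, also when adjusted over the list alone. Leaving out 1 CAL51 library gave between 1 and 16 genes, the highest without gefitinib replicate 1, and 8 of the 11 libraries moved the count by over 1.5 times. PHLDA1-AS1 did not pass under 13 of 24 alternatives and CYP1A1 under 2, with adjusted p up to 0.438 and 0.122 by limma with Benjamini-Hochberg adjustment.

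THZ531 against DMSO asked what inhibition of CDK12 and CDK13 alone does. In CAL51, MYC (ENSG00000136997.13, chromosome 8, 127735434 to 127741434, plus strand) rose from 18.3 ± 2.18 to 105 ± 6.5 TPM (SD, n = 3 each), a log2 change of 2.46 ± 0.10 (limma, Benjamini-Hochberg adjusted p = 1.8e-07). HEXIM1, which holds the elongation kinase P-TEFb in an inactive complex (ENSG00000186834.3, chromosome 17, 45148502 to 45152101, plus strand), rose by 2.72 ± 0.10, and RGS16, a regulator of G-protein signalling, rose by 4.83 ± 0.11, from 0.805 ± 0.0825 to 50.3 ± 2.19 TPM (SD, n = 3 each). EGFR (ENSG00000146648.14, chromosome 7, 55019021 to 55211628, plus strand) fell from 5.98 ± 0.435 to 2.96 ± 0.348 TPM, a change of -0.82 ± 0.12 (limma, Benjamini-Hochberg adjusted p = 1.9e-04). CDK12, the kinase targeted (ENSG00000167258.12, chromosome 17, 39461511 to 39564907, plus strand), fell from 17.9 ± 1.07 to 8.19 ± 1.71 TPM, a change of -1.06 ± 0.14 (limma, Benjamini-Hochberg adjusted p = 1.3e-04), while CDK13 (-0.28 ± 0.18) and CCNK (-0.16 ± 0.18) did not pass and passed as lower under both other scalings. Among genes that rose most were the small RNA genes SNORD3A (8.72 ± 0.33), a U3 small nucleolar RNA, and RNU2-2P (7.52 ± 0.93), a U2 small nuclear RNA gene. Both belong to families of near-identical copies, so their values are uncertain, and WDR74 (4.30 ± 0.21) shares its start with RNU2-2P and is uncertain too. Among genes that fell most were ZNF76 (-2.40 ± 0.13), WDR91 (-2.27 ± 0.12), KRCC1 (-2.23 ± 0.13) and TCAF1 (-2.12 ± 0.19).

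In MDA-MB-231, HEXIM1 rose from 34.2 ± 1.8 to 801 ± 50.1 TPM (SD, n = 3 each), a log2 change of 4.51 ± 0.08 (limma, Benjamini-Hochberg adjusted p = 2.1e-11). KRT17, a basal keratin, rose by 5.58 ± 0.12, ID2, an inhibitor of basic helix-loop-helix factors, by 5.23 ± 0.14, the keratin-associated protein gene KRTAP2-3 by 5.22 ± 0.09 and RHOB, a small GTPase, by 4.51 ± 0.07. EGFR fell from 20 ± 1.37 to 8.29 ± 1.12 TPM (-1.18 ± 0.16) and CDK12 from 18 ± 0.969 to 3.15 ± 0.385 TPM (-2.20 ± 0.09), with limma and Benjamini-Hochberg adjusted p = 4.1e-05 and 3.4e-09. MYC rose by 0.85 ± 0.11 with TMM scaling, by 0.12 without passing in TPM as deposited, and had a change of -0.44 that did not pass under spike-in scaling, so its direction depended on the scaling. The same held for CDK13 (0.53 ± 0.12 with TMM, -0.14 as deposited and -0.64 with spike-ins) and CCNK (0.39 ± 0.10, -0.33 and -0.88), where CCNK passed as lower with summed spike-ins (-0.92) and with TPM as deposited without the rRNA-rich libraries (-0.63). ZNF76 (-3.47 ± 0.16), CHTF8 (-3.24 ± 0.15), PILRB (-3.22 ± 0.17) and NPIPB5 (-3.51 ± 0.15) were among those that fell most, NPIPB5 belonging to a family of near-identical copies. The small RNA genes SNORD3B-1 (6.50 ± 0.22) and RNU2-2P (7.29 ± 1.84) rose, as did WDR74 (4.47 ± 0.08).

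By limma with Benjamini-Hochberg adjustment, 6760 genes rose and 4995 fell among 19797 in CAL51, and 7123 rose and 5705 fell among 17181 in MDA-MB-231. With TPM as deposited the split was 3754 higher and 9796 lower in CAL51 and 2896 and 7002 in MDA-MB-231. With spike-in scaling it was 1844 and 10067 in CAL51 and 1798 and 9050 in MDA-MB-231. An absolute log2 change above 1 left 4079 genes in CAL51 and 5411 in MDA-MB-231. Of the genes named for THZ531, IER3, TRIAP1, CITED2, PLK1, CDC20, NOP56, NOP2, RPLP2, RPS15 and MT-ND1 in CAL51 and CDK13, CCNK, MYC, PHLDA1, UBE2C, BBC3, TRIAP1, ASNS, RPS15 and MT-ND3 in MDA-MB-231 did not pass under spike-in scaling.

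**Figure D1:**
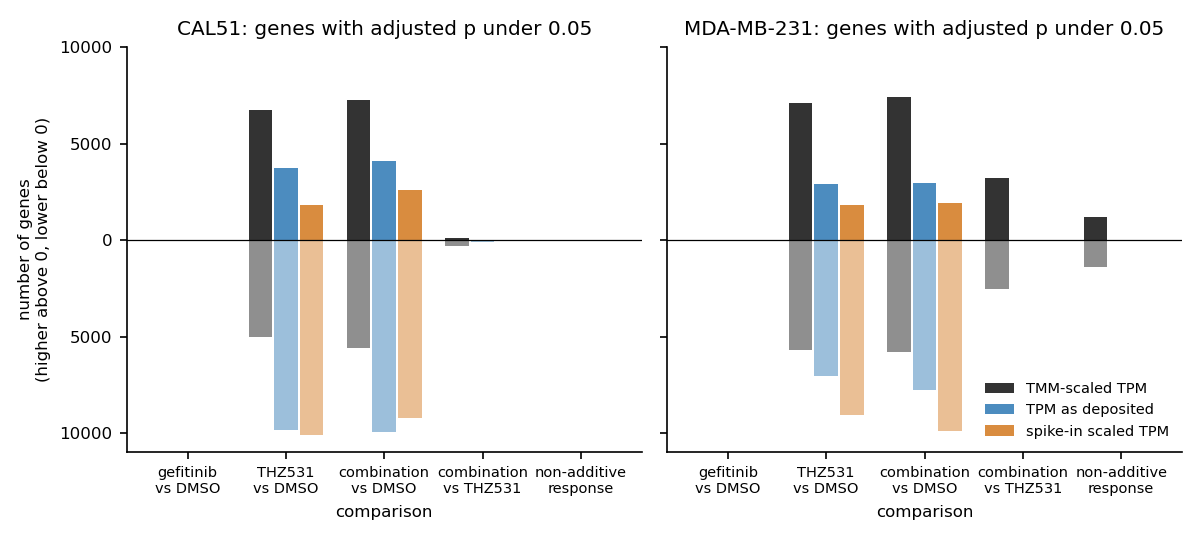
Numbers of genes with adjusted p under 0.05 (limma, Benjamini-Hochberg) on the vertical axis, higher above 0 and lower below 0, for 5 comparisons in each line, with bars for TMM-scaled TPM, TPM as deposited and spike-in scaled TPM. Under THZ531 in CAL51 the bars stand at 6760 higher and 4995 lower with TMM, and at 1844 and 10067 with spike-ins, so the balance turns, as it does with TPM as deposited.

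DNA damage repair genes fell in both lines with TMM scaling. They stayed lower under the other scalings, which could hardly have turned this, since both lower genes as a whole. In CAL51 2 of 30 measured members rose, 22 fell and 6 did not pass (25 passed adjusted over the list alone) (limma camera, Benjamini-Hochberg adjusted p = 3.5e-05, and adjusted p = 0.0411 with an estimated correlation). XRCC2, which acts in homologous recombination, fell by 1.49 ± 0.18 and the checkpoint kinase ATR by 1.03 ± 0.18. In MDA-MB-231 4 of 30 measured members rose, 19 fell and 7 did not pass (23 passed adjusted over the list alone) (limma camera, Benjamini-Hochberg adjusted p = 0.0022, and adjusted p = 0.46 with an estimated correlation). XRCC2 changed by -2.18 ± 0.11 and the helicase BLM by -1.83 ± 0.14. TPM as deposited gave 26 and 24 lower members, where 9796 and 7002 of all genes were lower. Spike-in scaling gave 27 and 27, where 10067 and 9050 of all genes were lower. For the G2/M and mitosis list in MDA-MB-231 3 of 26 measured members rose, 19 fell and 4 did not pass (22 passed adjusted over the list alone) (limma camera, Benjamini-Hochberg adjusted p = 1.2e-04, and adjusted p = 0.409 with an estimated correlation), with the mitotic kinases AURKB (-1.74 ± 0.06) and BUB1 (-1.61 ± 0.08) and cyclin CCNB1 (-1.61 ± 0.08) lower and the ubiquitin-conjugating enzyme UBE2C higher (1.93 ± 0.11). 20 of its members fell in TPM as deposited and 24 under spike-in scaling. The CAL51 members went both ways: 11 of 26 measured members rose, 8 fell and 7 did not pass (19 passed adjusted over the list alone), with UBE2C (2.28 ± 0.16), PLK1 (1.53 ± 0.08) and CDC20 (1.47 ± 0.14) higher. Its median (-0.07), mean (0.22) and test (up) differed in sign, and 4 rose and 16 fell in TPM as deposited, and 1 rose and 16 fell under spike-in scaling, so that the balance turned in TPM as deposited and under spike-in scaling. The G1/S and DNA replication list was split, as 7 of 28 rose and 13 fell (21 passed adjusted over the list alone, with 1 and 23 in TPM as deposited, 0 and 22 under spike-in scaling) in CAL51. In MDA-MB-231 10 of 28 rose and 10 fell (20 passed adjusted over the list alone, with 1 and 13 in TPM as deposited, 0 and 20 under spike-in scaling).

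Immediate-early and short-lived mRNAs rose in both lines. In CAL51 20 of 25 measured members rose, 1 fell and 4 did not pass (21 passed adjusted over the list alone) (limma camera, Benjamini-Hochberg adjusted p = 5.7e-05, and adjusted p = 0.353 with an estimated correlation). The AP-1 subunit JUNB changed by 2.93 ± 0.22 and IER2 by 2.46 ± 0.19. In MDA-MB-231 20 of 25 measured members rose, 1 fell and 4 did not pass (21 passed adjusted over the list alone) (limma camera, Benjamini-Hochberg adjusted p = 2.5e-04, and adjusted p = 0.478 with an estimated correlation). JUNB changed by 3.82 ± 0.16 and ID2 by 5.23 ± 0.14. 10 and 9 members rose and 4 and 2 fell in TPM as deposited, and 8 and 8 rose and 4 and 4 fell under spike-in scaling. Of the ERK pathway output list, 13 of 21 rose and 3 fell (16 passed adjusted over the list alone, with 5 and 8 in TPM as deposited, 3 and 8 under spike-in scaling) in CAL51 (limma camera, Benjamini-Hochberg adjusted p = 0.0332, and adjusted p = 0.353 with an estimated correlation). Its balance turned under both other scalings. PHLDA1 (2.48 ± 0.11), IER3 (2.04 ± 0.15) and the AP-1 subunit FOSL1 (2.63 ± 0.18) rose. In MDA-MB-231 11 of 22 rose and 4 fell (15 passed adjusted over the list alone, with 5 and 5 in TPM as deposited, 2 and 11 under spike-in scaling). The balance turned under spike-in scaling, with EPHA4 (3.54 ± 0.16), IER3 (2.59 ± 0.08) and PHLDA1 (1.77 ± 0.07) higher and FOSL1 (-2.01 ± 0.10) lower. The FOXO-linked and PI3K feedback list rose with TMM scaling. In CAL51 13 of 22 rose and 3 fell (17 passed adjusted over the list alone, with 6 and 7 in TPM as deposited, 3 and 7 under spike-in scaling) (limma camera, Benjamini-Hochberg adjusted p = 0.0293, and adjusted p = 0.24 with an estimated correlation). Higher members included TXNIP (2.18 ± 0.09) and CITED2 (1.94 ± 0.12) and the balance turned under both other scalings. In MDA-MB-231 14 of 21 rose and 3 fell (17 passed adjusted over the list alone, with 10 and 4 in TPM as deposited, 6 and 5 under spike-in scaling) (limma camera, Benjamini-Hochberg adjusted p = 0.0241, and adjusted p = 0.403 with an estimated correlation). CITED2 changed by 3.63 ± 0.14 and TXNIP by 2.43 ± 0.07.

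Cytosolic ribosomal protein mRNAs rose together with TMM scaling. In CAL51 72 of 75 measured members rose, 0 fell and 3 did not pass (73 passed adjusted over the list alone) (limma camera, Benjamini-Hochberg adjusted p = 3.3e-11, and adjusted p = 0.61 with an estimated correlation), with RPLP2 at 1.75 ± 0.24 and RPS15 at 1.70 ± 0.21. For these, 15 rose and 7 fell in TPM as deposited, and 0 rose and 2 fell under spike-in scaling, so that the balance turned under spike-in scaling. In MDA-MB-231 75 of 75 measured members rose, 0 fell and 0 did not pass (75 passed adjusted over the list alone) (limma camera, Benjamini-Hochberg adjusted p = 2.2e-10, and adjusted p = 0.635 with an estimated correlation), with RPS15 at 2.05 ± 0.20. Of the list, 9 rose and 0 fell in TPM as deposited, and 0 rose and 0 fell under spike-in scaling. All 13 mitochondrially encoded mRNAs rose in each line with TMM, also when adjusted over the list alone. MT-ND1 stood at 1.51 ± 0.20 in CAL51 (limma camera, Benjamini-Hochberg adjusted p = 1.6e-04, and adjusted p = 0.445 with an estimated correlation). MT-ND3 stood at 1.56 ± 0.22 in MDA-MB-231 (limma camera, Benjamini-Hochberg adjusted p = 0.0023, and adjusted p = 0.64 with an estimated correlation). 11 of them rose in CAL51 and 0 in MDA-MB-231 in TPM as deposited, and none in either line under spike-in scaling. Relative to the median of all genes, the ribosomal protein list stood 0.75 and 1.14 higher with TMM and 0.37 and 0.79 higher with spike-ins. MYC targets and ribosome biogenesis genes rose in CAL51 with TMM. There 18 of 32 rose and 1 fell (19 passed adjusted over the list alone, with 6 and 17 in TPM as deposited, 1 and 16 under spike-in scaling) (limma camera, Benjamini-Hochberg adjusted p = 0.0065, and adjusted p = 0.326 with an estimated correlation), with the nucleolar proteins NOP56 (2.20 ± 0.17) and NOP2 (1.89 ± 0.08) higher, and the balance turned under both other scalings. In MDA-MB-231 15 of 31 rose and 9 fell (24 passed adjusted over the list alone, with 4 and 12 in TPM as deposited, 2 and 19 under spike-in scaling), again turning under both.

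The p53 target list went both ways. In CAL51 12 of 27 rose and 7 fell (19 passed adjusted over the list alone, with 5 and 17 in TPM as deposited, 3 and 16 under spike-in scaling). The balance turned under both other scalings, and GDF15 (3.01 ± 0.10), the pro-apoptotic BBC3 (2.58 ± 0.22), the cell cycle inhibitor CDKN1A (2.43 ± 0.11) and TRIAP1 (2.08 ± 0.11) were higher. In MDA-MB-231 9 of 26 rose and 11 fell (20 passed adjusted over the list alone, with 5 and 13 in TPM as deposited, 0 and 17 under spike-in scaling), with TRIAP1 (1.96 ± 0.13) and BBC3 (1.89 ± 0.13) higher, and median (-0.14), mean (0.06) and test (down) that differed in sign. Targets of ATF4 fell in CAL51, where 6 of 24 measured members rose, 13 fell and 5 did not pass (20 passed adjusted over the list alone) (limma camera, Benjamini-Hochberg adjusted p = 0.0345, and adjusted p = 0.24 with an estimated correlation). The folate enzyme MTHFD2 (-1.36 ± 0.10) and the cystine transporter SLC7A11 (-1.33 ± 0.14) were lower. In MDA-MB-231 14 of 24 rose and 3 fell (17 passed adjusted over the list alone, with 6 and 4 in TPM as deposited, 2 and 9 under spike-in scaling). There DDIT4 (2.37 ± 0.08) and asparagine synthetase ASNS (1.71 ± 0.11) were higher and the balance turned under spike-in scaling. Of NF-kB targets and cytokines, 9 of 21 rose and 4 fell (13 passed adjusted over the list alone, with 4 and 11 in TPM as deposited, 1 and 10 under spike-in scaling) in CAL51. In MDA-MB-231 13 of 25 rose and 9 fell (22 passed adjusted over the list alone, with 6 and 11 in TPM as deposited, 4 and 11 under spike-in scaling). The chemokine CCL20 rose there by 4.92 ± 0.12 and IL6 by 2.89 ± 0.11, the balance turning under both other scalings in both lines.

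The CDK12/13 and transcription elongation list was split, as 9 of 29 rose and 7 fell (16 passed adjusted over the list alone, with 5 and 17 in TPM as deposited, 1 and 18 under spike-in scaling) in CAL51. In MDA-MB-231 12 of 29 rose and 12 fell (24 passed adjusted over the list alone, with 5 and 13 in TPM as deposited, 1 and 17 under spike-in scaling). In CAL51 the balance turned under both other scalings. Its median, mean and test differed in sign in CAL51 (median -0.10, mean 0.24, test direction up) and in MDA-MB-231 (median 0.08, mean 0.21, test direction down). Of the MYC stability regulators, 10 of 22 rose and 3 fell (13 passed adjusted over the list alone, with 3 and 13 in TPM as deposited, 0 and 13 under spike-in scaling) in CAL51. In MDA-MB-231 10 of 22 rose and 7 fell (17 passed adjusted over the list alone, with 1 and 8 in TPM as deposited, 0 and 11 under spike-in scaling), the balance turning under both other scalings in each. ERBB receptors and ligands had 3 members higher and 3 lower of 10 in CAL51 (median -0.08, mean 0.06, test direction down, 6 passing when adjusted over the list alone). In MDA-MB-231 4 rose and 5 fell of 13 (9 passing when adjusted over the list alone), with 7 and 7 lower under spike-in scaling. For translation initiation and mTOR genes, 9 of 32 rose and 13 fell (22 passed adjusted over the list alone, with 3 and 22 in TPM as deposited, 0 and 22 under spike-in scaling) in CAL51. In MDA-MB-231 11 of 31 rose and 15 fell (27 passed adjusted over the list alone, with 2 and 18 in TPM as deposited, 0 and 21 under spike-in scaling). Cholesterol synthesis genes rose more than they fell with TMM, 9 against 3 of 24 in CAL51 and 12 against 3 of 23 in MDA-MB-231 (12 and 15 passing when adjusted over the list alone). This turned in both lines, with 0 rising and 17 and 7 falling in TPM as deposited, and 0 rising and 17 and 12 falling under spike-in scaling.

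**Figure D2:**
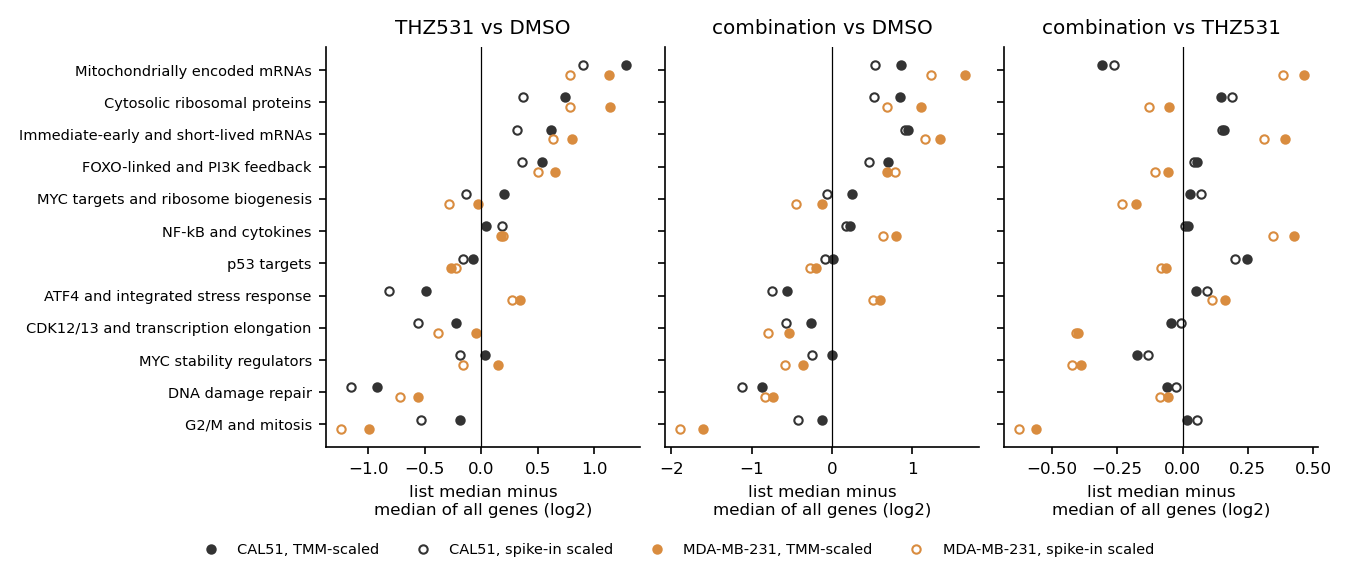
List median minus the median of all tested genes (log2, horizontal axis) for 12 gene lists in the 2 lines, under THZ531 and the combination against DMSO and the combination against THZ531, with filled points for TMM scaling and open points for spike-in scaling. DNA damage repair stands at -0.92 in CAL51 and -0.56 in MDA-MB-231 under THZ531, and cytosolic ribosomal proteins at 0.75 and 1.14, whose absolute direction is lost with spike-ins, where 0 members rose in either line.

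The combination against DMSO asked what joint inhibition does. MYC rose in CAL51 from 18.3 ± 2.18 to 157 ± 11.1 TPM (SD, n = 3 each), a log2 change of 3.04 ± 0.10 (limma, Benjamini-Hochberg adjusted p = 4.8e-08). In MDA-MB-231 it rose from 75.7 ± 3.83 to 255 ± 36.6 TPM, a change of 1.73 ± 0.11 (limma, Benjamini-Hochberg adjusted p = 6.7e-08), which did not pass in TPM as deposited (0.80) or under spike-in scaling (0.20). EGFR fell by 0.96 ± 0.12 in CAL51 and 1.12 ± 0.16 in MDA-MB-231, and CDK12 by 1.15 ± 0.14 and 1.86 ± 0.09. CDK13 did not pass in either line (0.03 ± 0.18 and 0.25 ± 0.12) but passed as lower in both under spike-in scaling, and CCNK fell in MDA-MB-231 (-0.37 ± 0.10) without passing in CAL51 (-0.13 ± 0.18). In CAL51, RGS16 (5.39 ± 0.11), the stress-response gene GADD45B (4.53 ± 0.10), GDF15 (3.16 ± 0.10) and CDKN1A (2.79 ± 0.11) rose, and KRCC1 (-3.09 ± 0.13), the transcription factor PAX8 (-2.86 ± 0.12) and the nuclease LACTB2 (-2.71 ± 0.10) fell. In MDA-MB-231, KRTAP2-3 (6.35 ± 0.09), ID2 (6.17 ± 0.14), JUNB (5.11 ± 0.16) and HEXIM1 (4.80 ± 0.08) rose, and the mitotic kinesin KIF18B (-3.71 ± 0.14), the glycosyltransferase GCNT1 (-3.62 ± 0.24) and the TNF receptor TNFRSF1A (-3.59 ± 0.14) fell. HEXIM1 rose by 2.88 ± 0.10 and JUNB by 3.26 ± 0.22 in CAL51. The small RNA genes SNORD3A (8.74 ± 0.33) and RNU2-2P (8.20 ± 0.93) rose in CAL51, and RNU2-2P (7.56 ± 1.84) rose in MDA-MB-231.

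**Figure D3:**
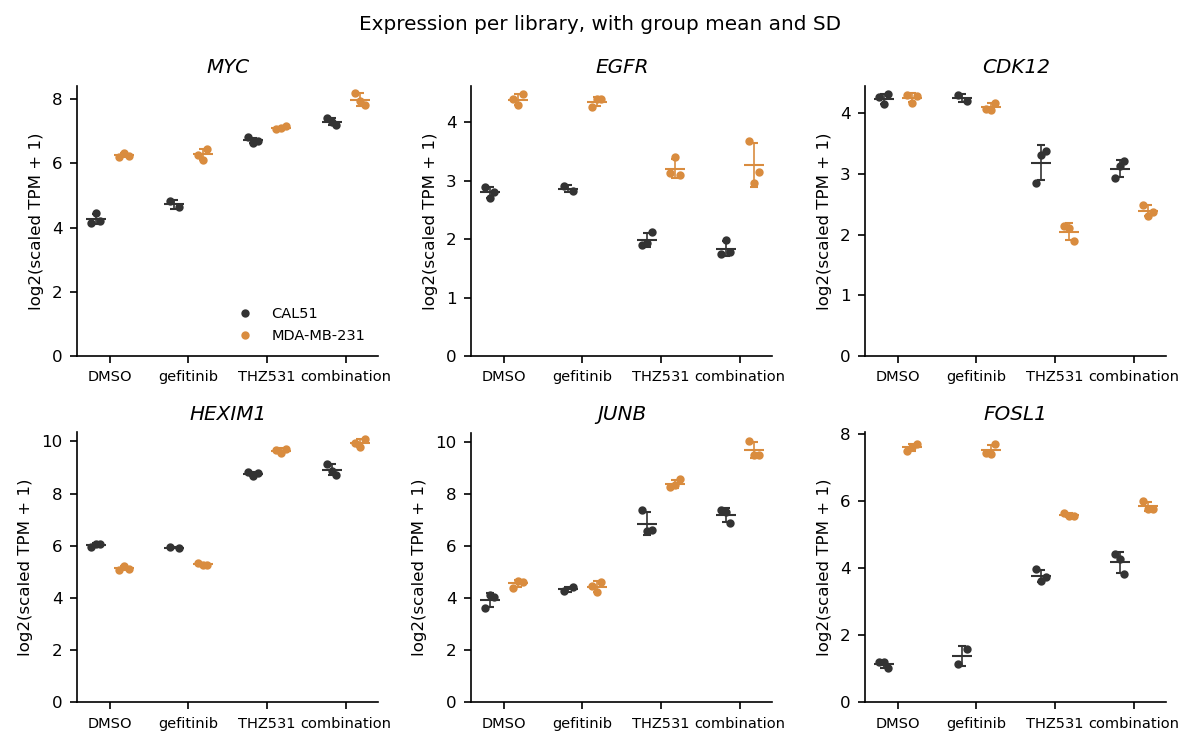
Expression of MYC, EGFR, CDK12, HEXIM1, JUNB and FOSL1 in each library as log2(TMM-scaled TPM + 1), with a point per library and a cross bar with error bar for the group mean and SD, by treatment and line. EGFR and CDK12 lie below DMSO with THZ531 and the combination in both lines, MYC lies above it, which turns to -0.44 for THZ531 in MDA-MB-231 under spike-in scaling, and FOSL1 lies above DMSO with THZ531 in CAL51 and below it in MDA-MB-231.

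Repair genes fell here too. In CAL51 2 of 30 measured members rose, 23 fell and 5 did not pass (25 passed adjusted over the list alone) (limma camera, Benjamini-Hochberg adjusted p = 5.0e-05, and adjusted p = 0.0411 with an estimated correlation), with BLM at -1.80 ± 0.17 and BRCA2 at -1.42 ± 0.24. In MDA-MB-231 1 of 30 measured members rose, 18 fell and 11 did not pass (18 passed adjusted over the list alone) (limma camera, Benjamini-Hochberg adjusted p = 0.0036, and adjusted p = 0.46 with an estimated correlation). BLM changed by -1.99 ± 0.14. Both other scalings kept the direction, with 27 and 29 lower under spike-in scaling. As they lower genes as a whole, they could hardly have turned it. Mitotic genes fell in MDA-MB-231, where 1 of 26 measured members rose, 23 fell and 2 did not pass (24 passed adjusted over the list alone) (limma camera, Benjamini-Hochberg adjusted p = 1.4e-07, and adjusted p = 0.22 with an estimated correlation). Among them were the kinesin KIF11 (-2.83 ± 0.12), topoisomerase TOP2A (-2.05 ± 0.08) and CCNB1 (-1.98 ± 0.08), and 25 fell under spike-in scaling. In CAL51 10 of 26 rose and 6 fell (16 passed adjusted over the list alone, with 4 and 16 in TPM as deposited, 1 and 15 under spike-in scaling), turning under both other scalings. Immediate-early genes rose, as 18 of 25 rose and 2 fell (20 passed adjusted over the list alone, with 13 and 6 in TPM as deposited, 7 and 3 under spike-in scaling) in CAL51 (limma camera, Benjamini-Hochberg adjusted p = 2.6e-04, and adjusted p = 0.392 with an estimated correlation). In MDA-MB-231 23 of 25 rose and 2 fell (25 passed adjusted over the list alone, with 12 and 2 in TPM as deposited, 9 and 5 under spike-in scaling) (limma camera, Benjamini-Hochberg adjusted p = 1.1e-05, and adjusted p = 0.46 with an estimated correlation). For NF-kB targets and cytokines in MDA-MB-231, 17 of 25 rose and 8 fell (25 passed adjusted over the list alone, with 8 and 8 in TPM as deposited, 5 and 10 under spike-in scaling). That balance turned under spike-in scaling, with IL6 (3.24 ± 0.11) and the feedback inhibitor TNFAIP3 (3.01 ± 0.13) higher. Of ATF4 targets, 7 of 24 rose and 12 fell (19 passed adjusted over the list alone, with 4 and 18 in TPM as deposited, 0 and 17 under spike-in scaling) in CAL51. In MDA-MB-231 17 of 24 rose and 5 fell (22 passed adjusted over the list alone, with 9 and 7 in TPM as deposited, 4 and 11 under spike-in scaling), with DDIT4 (2.22 ± 0.08) rising, and the balance turned under spike-in scaling. DDIT4 did not pass there (0.71), and of the other genes named as risen or fallen under the combination only MYC in MDA-MB-231 did not. All 13 mitochondrially encoded mRNAs rose in each line with TMM, 5 and 2 in TPM as deposited and none under spike-in scaling. The list had limma camera, Benjamini-Hochberg adjusted p = 0.0038 in CAL51 and 6.7e-04 in MDA-MB-231 (0.599 and 0.61 with an estimated correlation). Ribosomal protein mRNAs rose in 73 and 75 of 75 cases with TMM (limma camera, Benjamini-Hochberg adjusted p = 2.5e-11, and adjusted p = 0.608 with an estimated correlation in CAL51), but 0 rose in either line under spike-in scaling. The counts were 7243 genes higher and 5589 lower in CAL51 and 7437 and 5770 in MDA-MB-231 (limma, Benjamini-Hochberg). With TPM as deposited they were 4100 and 9906 in CAL51 and 2950 and 7752 in MDA-MB-231. Under spike-in scaling they were 2579 and 9219 in CAL51 and 1925 and 9888 in MDA-MB-231. An absolute log2 change above 1 left 5395 and 6134.

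The combination against THZ531 asked what gefitinib adds once CDK12 and CDK13 are inhibited. In MDA-MB-231, MYC rose from 137 ± 3.92 to 255 ± 36.6 TPM (SD, n = 3 each), a log2 change of 0.88 ± 0.11 (limma, Benjamini-Hochberg adjusted p = 2.2e-04). The cytokine LIF (1.33 ± 0.15), the transporter ABCC3 (1.32 ± 0.19) and JUNB (1.29 ± 0.16) were among the genes that rose most, and JUN (1.04 ± 0.11) and the ERK feedback inhibitor SPRY4 (0.97 ± 0.12) rose too. CDCA4 (-1.78 ± 0.10), the ubiquitin-conjugating enzyme UBE2O (-1.77 ± 0.12), the calcineurin subunit PPP3R1 (-1.75 ± 0.13), the dynein regulator PAFAH1B1 (-1.72 ± 0.13) and the phosphatase CTDSP2 (-1.72 ± 0.14) were among those that fell most. In CAL51, CYP1A1 rose by 1.05 ± 0.09 (limma, Benjamini-Hochberg adjusted p = 0.003), ID2 by 0.84 ± 0.13 and GADD45B by 0.74 ± 0.10, and NPIPB3, of a family of near-identical copies, fell by 1.27 ± 0.27. Of 25 alternatives, CYP1A1 did not pass in 3, ID2 in 15, GADD45B in 8 and NPIPB3 in 15.

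Mitotic genes fell further in MDA-MB-231, where 0 of 26 measured members rose, 19 fell and 7 did not pass (20 passed adjusted over the list alone) (limma camera, Benjamini-Hochberg adjusted p = 5.4e-10, and adjusted p = 0.204 with an estimated correlation). KIF11 (-1.42 ± 0.12), the mitotic kinase AURKA (-1.28 ± 0.07) and its activator TPX2 (-1.12 ± 0.06) were lower. Transcription elongation genes fell as well: 4 of 29 measured members rose, 14 fell and 11 did not pass (20 passed adjusted over the list alone) (limma camera, Benjamini-Hochberg adjusted p = 3.1e-04, and adjusted p = 0.165 with an estimated correlation). Among them were CDK7, the kinase of the CDK-activating complex (-1.16 ± 0.13), and the elongation factor ELL (-0.85 ± 0.13). Of the MYC stability regulators, 1 of 22 measured members rose, 9 fell and 12 did not pass (11 passed adjusted over the list alone) (limma camera, Benjamini-Hochberg adjusted p = 5.4e-04, and adjusted p = 0.165 with an estimated correlation). AURKA and the deubiquitinase USP7 (-1.26 ± 0.07) were lower. Immediate-early genes rose: 18 of 25 measured members rose, 0 fell and 7 did not pass (18 passed adjusted over the list alone) (limma camera, Benjamini-Hochberg adjusted p = 1.1e-05, and adjusted p = 0.46 with an estimated correlation). NF-kB targets and cytokines rose: 18 of 25 measured members rose, 1 fell and 6 did not pass (19 passed adjusted over the list alone) (limma camera, Benjamini-Hochberg adjusted p = 1.2e-04, and adjusted p = 0.22 with an estimated correlation). Among them were CCL2 (1.13 ± 0.11) and TNF (0.78 ± 0.11). For cholesterol synthesis genes 2 of 23 measured members rose, 9 fell and 12 did not pass (11 passed adjusted over the list alone) (limma camera, Benjamini-Hochberg adjusted p = 0.032, and adjusted p = 0.236 with an estimated correlation). The mitochondrially encoded mRNAs rose: 10 of 13 measured members rose, 0 fell and 3 did not pass (10 passed adjusted over the list alone) (limma camera, Benjamini-Hochberg adjusted p = 0.0048, and adjusted p = 0.656 with an estimated correlation). MT-CO1 rose by 0.65 ± 0.13. For each of these MDA-MB-231 lists 0 members passed in TPM as deposited and 0 under spike-in scaling, where SE were larger. KIF11 was -1.49 ± 0.33 and AURKA -1.46 ± 0.35 in TPM as deposited. The rRNA-rich libraries, outside this comparison, entered the shared estimate of spread. Without them, 2472 of the 2542 MDA-MB-231 genes that fell and 722 of the 3214 that rose passed in TPM as deposited. Lists were not tested in that setting. In CAL51 the p53 target list stood higher: 1 of 27 measured members rose, 0 fell and 26 did not pass (8 passed adjusted over the list alone) (limma camera, Benjamini-Hochberg adjusted p = 0.002, and adjusted p = 0.13 with an estimated correlation). CCNG1 rose by 0.44 ± 0.10, but did not pass in 20 of 25 alternatives. The CAL51 G1/S and DNA replication list stood lower: 0 of 28 measured members rose, 3 fell and 25 did not pass (5 passed adjusted over the list alone) (limma camera, Benjamini-Hochberg adjusted p = 0.0219, and adjusted p = 0.284 with an estimated correlation). UHRF1 (-0.44 ± 0.09) and MCM3 (-0.37 ± 0.08) fell, without passing in 15 and 16 of 25 alternatives. CAL51 ribosomal protein mRNAs had a median of 0.15 with 0 of 75 passing (limma camera, Benjamini-Hochberg adjusted p = 8.9e-04, and adjusted p = 0.765 with an estimated correlation). Mitochondrially encoded mRNAs there had a median of -0.30 with 0 of 13 passing (limma camera, Benjamini-Hochberg adjusted p = 0.0063, and adjusted p = 0.62 with an estimated correlation). In these 4 CAL51 lists 0 members passed in TPM as deposited and 0 under spike-in scaling.

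In total 3214 genes rose and 2542 fell in MDA-MB-231, and 129 rose and 292 fell in CAL51 (limma, Benjamini-Hochberg). TPM as deposited left 5 higher and 39 lower in MDA-MB-231 and 24 and 99 in CAL51, and spike-in scaling 0 and 1, and 4 and 2. Over the genes that rose and fell in MDA-MB-231, the median change was 0.47 (SE 0.11) and -0.56 (SE 0.11) with TMM, 0.31 (SE 0.32) and -0.69 (SE 0.33) in TPM as deposited, and 0.25 (SE 0.38) and -0.69 (SE 0.40) under spike-in scaling (median SE in parentheses). Without the rRNA-rich libraries, none of which is in this comparison, TPM as deposited gave 743 higher and 3254 lower in MDA-MB-231, so the balance turned. For the genes named here the log2 changes stayed in direction, MYC in MDA-MB-231 being 0.69 in TPM as deposited and 0.64 under spike-in scaling, and none passed under spike-in scaling. The CAL51 count rested on single libraries and on the fit, as it was 4 with the 6 libraries of the comparison alone, 2 with replicate number as a block, 4846 with library weights, 41 without the rRNA-rich library, 4 without DMSO replicate 2 and 1181 without THZ531 replicate 1. Each CAL51 library but THZ531 replicate 3 moved it by over 1.5 times when left out. The difference between the lines was not tested.

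The combination against gefitinib asked what THZ531 adds to EGFR inhibition. In CAL51, RGS16 rose by 5.28 ± 0.12 (n = 3 against 2) and the U3 gene SNORD3C, of a family of near-identical copies, by 8.39 ± 0.29, and KRCC1 (-2.98 ± 0.14) and PAX8 (-2.88 ± 0.13) fell. In MDA-MB-231, KRTAP2-3 (6.29 ± 0.09, n = 3 against 3) and SNORD3C (6.64 ± 0.57) rose, and GCNT1 (-3.70 ± 0.24), KIF18B (-3.63 ± 0.14) and TNFRSF1A (-3.52 ± 0.14) fell. Repair genes fell in CAL51: 2 of 30 measured members rose, 21 fell and 7 did not pass (25 passed adjusted over the list alone) (limma camera, Benjamini-Hochberg adjusted p = 7.6e-05, and adjusted p = 0.0411 with an estimated correlation), and 28 fell under spike-in scaling. Of mitotic genes in MDA-MB-231, 1 of 26 measured members rose, 22 fell and 3 did not pass (23 passed adjusted over the list alone) (limma camera, Benjamini-Hochberg adjusted p = 1.4e-07, and adjusted p = 0.22 with an estimated correlation), and 25 fell under spike-in scaling. The counts were 6744 higher and 5178 lower in CAL51 and 7397 and 5751 in MDA-MB-231 (limma, Benjamini-Hochberg). They were 4072 and 8703, and 3135 and 6730, in TPM as deposited, and 1998 and 10987, and 1892 and 10306, under spike-in scaling.

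The interaction asked whether the combination differed from the sum of the single-drug log2 changes. In MDA-MB-231, LIF (1.49 ± 0.21), JUNB (1.41 ± 0.22), the transcription factor KLF6 (1.25 ± 0.08), SPRY4 (1.15 ± 0.16), CCL2 (0.99 ± 0.15) and MYC (0.86 ± 0.15, limma, Benjamini-Hochberg adjusted p = 0.0052) lay above the sum over 12 libraries. PPP3R1 (-1.91 ± 0.19), CDCA4 (-1.85 ± 0.14), PROSER2 (-1.82 ± 0.19), KIF11 (-1.35 ± 0.16), CDK7 (-1.32 ± 0.18), AURKA (-1.25 ± 0.10) and CCNK (-0.89 ± 0.14) lay below it. Of immediate-early genes 15 of 25 lay above and 0 below, with 17 passing when adjusted over the list alone (limma camera, Benjamini-Hochberg adjusted p = 1.7e-06, and adjusted p = 0.46 with an estimated correlation). NF-kB targets and cytokines had 13 above and 1 below of 25 (17 when adjusted over the list alone, limma camera, Benjamini-Hochberg adjusted p = 1.1e-05, and adjusted p = 0.204 with an estimated correlation). Mitotic genes had 0 above and 11 below of 26 (17 when adjusted over the list alone, limma camera, Benjamini-Hochberg adjusted p = 5.2e-09, and adjusted p = 0.204 with an estimated correlation). Transcription elongation genes had 2 above and 10 below of 29 (14 when adjusted over the list alone, limma camera, Benjamini-Hochberg adjusted p = 6.2e-04, and adjusted p = 0.165 with an estimated correlation). MYC stability regulators had 1 and 9 of 22 (10 when adjusted over the list alone, limma camera, Benjamini-Hochberg adjusted p = 6.2e-04, and adjusted p = 0.165 with an estimated correlation). In all, 1201 genes lay above and 1406 below. In CAL51 0 of 19797 genes passed by limma with Benjamini-Hochberg adjustment, 1745 had an unadjusted p under 0.05, and 960 passed with library weights, 12 without the filter and 5 under spike-in scaling. TPM as deposited left 3 above and 1 below in MDA-MB-231 and spike-in scaling 6 and 2, and no list named here had a member passing in either. Over the genes above and below the sum, the median was 0.64 (SE 0.15) and -0.70 (SE 0.14) with TMM, 0.60 (SE 0.45) and -0.65 (SE 0.47) in TPM as deposited, and 0.37 (SE 0.54) and -0.90 (SE 0.56) under spike-in scaling (median SE in parentheses). Without the rRNA-rich libraries TPM as deposited gave 220 above and 1069 below. The MDA-MB-231 count was 1683 without gefitinib replicate 1, 1679 without gefitinib replicate 2, 1702 without DMSO replicate 2 and 1735 without THZ531 replicate 2, and the difference between the lines was not tested.

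Responses of the lines were set side by side over the 15776 genes tested in both, each line having its own controls. HEXIM1, JUNB and WDR74 rose and CDK12, EGFR, ZNF76 and XRCC2 fell under THZ531 in both. Under THZ531 4524 genes rose in both lines, where independent lists would share 2285, 3457 fell in both, where independent lists would share 1499, and 384 passed in opposite directions. Spearman's rho of the log2 changes was 0.789 across genes, which are not independent replicates. Under the combination 4851 rose in both (2515 for independent lists), 3666 fell in both (1693) and 576 went in opposite directions, with rho 0.792. With spike-in scaling 983 rose and 7280 fell in both lines under THZ531, where independent lists would share 130 and 4829.

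Gene length was compared with the response because CDK12 is known to act on long genes. Across genes, which are not independent replicates, Spearman's rho between genomic span and log2 change under THZ531 was -0.437 in CAL51 and -0.325 in MDA-MB-231. Under the combination it was -0.408 and -0.398, and under gefitinib -0.0443 and -0.0806. The gefitinib values were not stable: in CAL51 rho was 0.0601 without gefitinib replicate 3, 0.219 with spike-in scaling and -0.16 with TPM as deposited, and in MDA-MB-231 it was -0.00281 without gefitinib replicate 3, -0.0266 without DMSO replicate 3 and -0.221 with TPM as deposited. Without the filter rho was -0.313 and -0.206 under THZ531 and -0.283 and -0.235 under the combination. In protein-coding genes alone the THZ531 values were -0.319 and -0.214. Exonic length in place of span gave -0.396 and -0.314 over all genes under THZ531. In protein-coding genes it gave -0.250 and -0.195, so genomic span and exonic length were not told apart. The relation was not monotonic, since in CAL51 the median change was 0.49 in the shortest quintile of protein-coding genes, -0.32 in the next to longest and -0.22 in the longest, and in MDA-MB-231 0.59, -0.34 and -0.04. Of the named genes, ATR (ENSG00000175054.13, chromosome 3, 142449235 to 142578826, minus strand) fell and IER3 (ENSG00000137331.11, chromosome 6, 30743199 to 30744554, minus strand) rose in CAL51, while KRT17 (ENSG00000128422.14, chromosome 17, 41619441 to 41624842, minus strand) rose in MDA-MB-231. Against the relation, the long gene EPHA4 (ENSG00000116106.10, chromosome 2, 221418027 to 221574202, minus strand) rose in MDA-MB-231, as did CDK13 with TMM scaling but not with TPM as deposited or spike-ins. In the combination against THZ531, rho was -0.277 in MDA-MB-231 and -0.105 in CAL51.

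**Figure D4:**
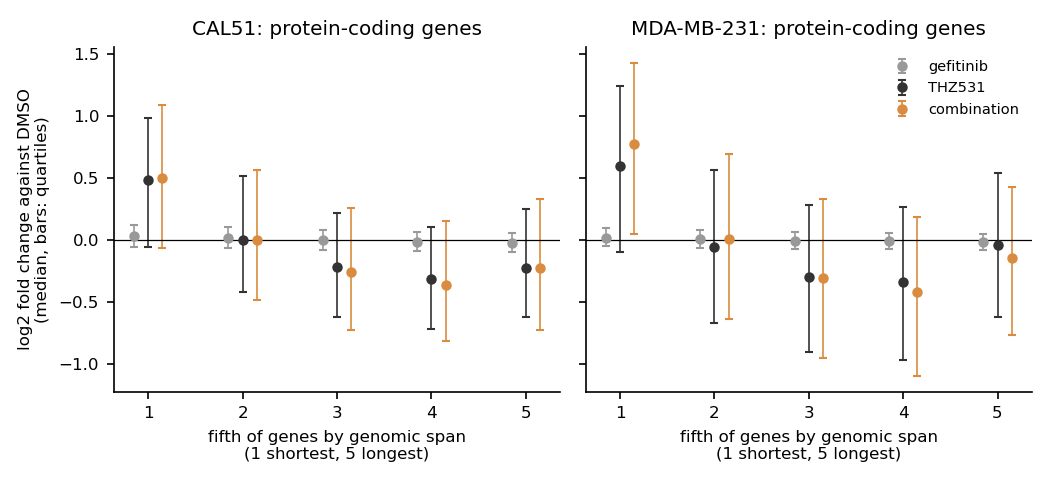
Median log2 fold change against DMSO (vertical axis, bars from the lower to the upper quartile of genes) of protein-coding genes in quintiles of genomic span from shortest to longest, for gefitinib, THZ531 and the combination in each line. The shortest quintile stands at 0.50 in CAL51 and 0.77 in MDA-MB-231 under the combination with TMM scaling and the next to longest at -0.36 and -0.42, while gefitinib stays between -0.02 and 0.03 in CAL51. The relation with length over all genes turned in sign for gefitinib in CAL51 under spike-in scaling.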

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

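The genes and lists here were chosen after their values were seen: every library of one line moved one way against its reference and every library of the other line the opposite way, and the differences between the lines were not tested. FOSL1 changed by 2.63 in CAL51 and -2.01 in MDA-MB-231 under THZ531, a difference of 4.65, with 1.64 and -3.29 under spike-in scaling. NPIPB3, with near-identical copies, changed by -1.27 and 0.32 when gefitinib was added to THZ531 (difference -1.59), the CAL51 change not passing in 15 of 25 alternatives, and MT-CO1 by -0.29, which did not pass, and 0.65 (difference -0.94). For lists the values are the mean log2 change less that of all tested genes. The mitochondrially encoded mRNAs had -0.31 in CAL51 and 0.46 in MDA-MB-231 (difference -0.771) when gefitinib was added to THZ531. Targets of ATF4 had -0.45 in CAL51 and 0.51 in MDA-MB-231 (difference -0.959) under THZ531. Under the combination they had -0.38 and 0.64 (-1.02), and for the combination against gefitinib -0.62 and 0.58 (-1.19). Targets of p53 had, in the same order, 0.12 and -0.10 (0.213), 0.31 and -0.12 (0.424), and 0.23 and -0.13 (0.355).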

How the results depend on the processing

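The alternatives with library weights, other pseudocounts, protein-coding genes, spike-in mixes and rRNA-rich libraries were chosen after the results were seen. Over gene lists, 5202 alternatives gave 4779 with the same call, 212 that no longer passed, 204 that now passed and 7 with the opposite sign. For named genes these were 4257 of 4531, 241, 22 and 11, and of 610 alternatives for counts and single values 105 moved. The cause was not tested for any of them. Median-of-ratios factors on TPM left 20 of 20 counts and single values and 177 of 178 named-gene calls the same. DESeq2 and edgeR need counts and were not run.

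In CAL51 and MDA-MB-231 a log2 change above 1 gave 54 and 271 for adding gefitinib to THZ531. For adding THZ531 to gefitinib it gave 5308 and 6047, for the combination 5395 and 6134 and for THZ531 4079 and 5411. It gave 3205 and 2361 genes in both lines under the combination and THZ531, and 296 for the interaction in MDA-MB-231. Library weights gave 4846 for adding gefitinib to THZ531 in CAL51, 6 and 1 for gefitinib in CAL51 and MDA-MB-231 and 960 for the interaction in CAL51. Without the filter there were 12 and 1 for gefitinib in CAL51 and MDA-MB-231 and 12 for the interaction in CAL51. Length rho in CAL51 and MDA-MB-231 was -0.283 and -0.235 for the combination and -0.313 and -0.206 for THZ531. Fits to only the groups compared gave 4 for adding gefitinib to THZ531 in CAL51 and 4 and 1 for gefitinib in CAL51 and MDA-MB-231. Protein-coding genes alone gave 1 and 1 for gefitinib in CAL51 and MDA-MB-231 and 1 for the interaction in CAL51. Length rho was -0.153 for gefitinib in CAL51, -0.303 for the combination in CAL51 and -0.318 and -0.213 for THZ531 in CAL51 and MDA-MB-231. A pseudocount of 0.1 gave 6 for gefitinib in MDA-MB-231, and one of 0.5 gave 1 for gefitinib in CAL51.

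With replicate number as a block there were 2 for adding gefitinib to THZ531 in CAL51 and 1 for gefitinib in CAL51. Whether the numbers pair the libraries is not stated in the labels. After group means were removed, 1 of 15 same-number pairs in CAL51 and 1 of 18 in MDA-MB-231 correlated above 0.1. That cannot exclude pairing, since the rRNA-rich libraries may hide what same-number libraries share.

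In CAL51 and MDA-MB-231, scaling by spike-ins adjusted for the mixes gave 6 and 1 for adding gefitinib to THZ531. It gave 13 and 9 for gefitinib and 5 and 8 for the interaction. Length rho was 0.219 for gefitinib in CAL51. Signs were opposite under THZ531 in MDA-MB-231 for CCNK (-0.88), CDK13 (-0.64) and MYC (-0.44). In CAL51 they were for the list G2/M and mitosis under gefitinib (-0.0020) and the list MYC targets and ribosome biogenesis for adding THZ531 to gefitinib (-0.19). Scaling by summed spike-ins gave 0 and 47 for adding gefitinib to THZ531 in CAL51 and MDA-MB-231, 6 for gefitinib in MDA-MB-231 and 3 for the interaction in MDA-MB-231. Length rho was 0.149 for gefitinib in CAL51. Signs were opposite under THZ531 in MDA-MB-231 for CCNK (-0.92, which passed as lower), CDK13 (-0.67) and MYC (-0.48). In CAL51 they were for the list MYC targets and ribosome biogenesis, for adding THZ531 to gefitinib (-0.17) and under THZ531 (-0.13). TPM as deposited gave 123 and 44 for adding gefitinib to THZ531 in CAL51 and MDA-MB-231, 3 for gefitinib in MDA-MB-231 and 4 for the interaction in MDA-MB-231. Length rho was -0.16 and -0.221 for gefitinib in CAL51 and MDA-MB-231. Signs were opposite for CCNK (-0.33) and CDK13 (-0.14) under THZ531 in MDA-MB-231. TPM as deposited without the rRNA-rich libraries gave 119 for adding gefitinib to THZ531 in CAL51, 10 for gefitinib in MDA-MB-231 and 1 and 1289 for the interaction in CAL51 and MDA-MB-231. Length rho was 0.101 for gefitinib in CAL51. Signs were opposite under THZ531 in MDA-MB-231 for CCNK (-0.63, which passed as lower), CDK13 (-0.39) and MYC (-0.19). Leaving out the rRNA-rich libraries alone gave 41 for adding gefitinib to THZ531 in CAL51, 3 for gefitinib in MDA-MB-231 and 1 for the interaction in CAL51. Length rho was 0.0601 for gefitinib in CAL51. Signs were opposite for the list Replication-dependent histones for the interaction in CAL51 (0.25). With mix-adjusted spike-ins and TMM-scaled RNA the ratios in CAL51 and MDA-MB-231 were -1.14 and -1.53 for the combination and -1.29 and -1.30 for THZ531. With mix-adjusted spike-ins and unscaled RNA they were -0.37 and -0.61, and -0.55 and -0.56.

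Leaving out 1 library at a time gave ranges of 1 to 16 for gefitinib in CAL51, 10208 to 12016 for THZ531 in CAL51, 11528 to 13769 for the combination in CAL51, 4 to 1181 for adding gefitinib to THZ531 in CAL51, 9536 to 12972 for adding THZ531 to gefitinib in CAL51, 0 to 11 for the interaction in CAL51, 0 to 2 for gefitinib in MDA-MB-231, 12137 to 13340 for THZ531 in MDA-MB-231, 12760 to 13499 for the combination in MDA-MB-231, 4201 to 5661 for adding gefitinib to THZ531 in MDA-MB-231, 12654 to 13398 for adding THZ531 to gefitinib in MDA-MB-231, 1679 to 2612 for the interaction in MDA-MB-231, 7236 to 8149 for genes in both lines under THZ531 and 7905 to 8987 for genes in both lines under the combination. For the spike-in ratios the CAL51 ranges were 0.17 to 0.50 (gefitinib), -0.74 to -0.42 (THZ531) and -0.79 to -0.26 (the combination). In MDA-MB-231 they were -0.25 to 0.47, -0.93 to -0.38 and -1.03 to -0.62 in that order. For length rho they were -0.13 to 0.0601, -0.453 to -0.389 and -0.428 to -0.385 in CAL51. In MDA-MB-231 they were -0.105 to -0.00281, -0.325 to -0.306 and -0.399 to -0.382. The interaction of the histone list in CAL51 ranged from -1.42 to 0.25 and turned in sign without gefitinib replicate 3. Ribosomal proteins under gefitinib in MDA-MB-231 ranged from -0.012 to 0.20 and turned in sign without DMSO replicate 3. Counts moved by over 1.5 times for gefitinib in CAL51 (6 without DMSO replicate 1, 4 without DMSO replicate 3, 16 without gefitinib replicate 1 and 1 without THZ531 replicate 1 or 2 or combination replicate 1 or 2 or 3), for adding gefitinib to THZ531 in CAL51 (5 without DMSO replicate 1, 4 without DMSO replicate 2, 18 without DMSO replicate 3, 41 without gefitinib replicate 1 or 3, 1181 without THZ531 replicate 1, 42 without THZ531 replicate 2, 117 without combination replicate 1, 14 without combination replicate 2 and 914 without combination replicate 3), for the interaction in CAL51 (2 without DMSO replicate 1 or THZ531 replicate 3 or combination replicate 3, 3 without DMSO replicate 3 or combination replicate 2, 1 without gefitinib replicate 3 or THZ531 replicate 2, 11 without THZ531 replicate 1 and 8 without combination replicate 1), for gefitinib in MDA-MB-231 (1 without DMSO replicate 1 or 2 or 3 and 2 without gefitinib replicate 1 or 2 or 3) and for the interaction in MDA-MB-231 (1702 without DMSO replicate 2, 1683 without gefitinib replicate 1, 1679 without gefitinib replicate 2 and 1735 without THZ531 replicate 2). Length rho for gefitinib in CAL51 was 0.0601 without gefitinib replicate 3. A group left with 1 library is assumed to vary like the others.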

Other observations

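Lists not described above were planned, while the tests on genes low in the rRNA-rich libraries, on the direction of fold changes under spike-in scaling, on resampled ratios of short genes and on regroupings within THZ531 levels were chosen after the result was seen. Of replication-dependent histone mRNAs, most of which lack a poly(A) tail, 9 of 12 rose and 0 fell under THZ531 with TMM in CAL51 (9 passed adjusted over the list alone, with 5 and 0 in TPM as deposited, 2 and 0 under spike-in scaling). In MDA-MB-231 4 of 11 rose and 0 fell (4 passed adjusted over the list alone, with 5 and 0 in TPM as deposited, 1 and 0 under spike-in scaling). That is no larger a share than over all genes in MDA-MB-231, of which 7123 of 17181 rose. Of YAP/TAZ targets 14 of 23 rose and 4 fell (18 passed adjusted over the list alone, with 8 and 10 in TPM as deposited, 2 and 9 under spike-in scaling) in CAL51. In MDA-MB-231 14 of 24 rose and 8 fell (22 passed adjusted over the list alone, with 6 and 9 in TPM as deposited, 1 and 10 under spike-in scaling), the balance turning under both other scalings in each line. Interferon response genes were split, as 6 of 16 rose and 6 fell (12 passed adjusted over the list alone, with 3 and 7 in TPM as deposited, 1 and 7 under spike-in scaling) in CAL51 (median 0.06, mean 0.24, test direction down). In MDA-MB-231 9 of 21 rose and 9 fell (18 passed adjusted over the list alone, with 5 and 10 in TPM as deposited, 3 and 10 under spike-in scaling). Apoptosis regulators were split, as 7 of 20 rose and 6 fell (13 passed adjusted over the list alone, with 2 and 14 in TPM as deposited, 1 and 12 under spike-in scaling) in CAL51 (median 0.09, mean 0.12, test direction down), turning under both other scalings. In MDA-MB-231 8 of 21 rose and 8 fell (16 passed adjusted over the list alone, with 4 and 8 in TPM as deposited, 2 and 14 under spike-in scaling) (median 0.00, mean 0.01, test direction down).

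Marker lists of other cell types had few measured members. Of luminal epithelial markers 8 of 9 rose and 0 fell (8 passed adjusted over the list alone, with 3 and 2 in TPM as deposited, 0 and 2 under spike-in scaling) in CAL51, turning under spike-in scaling. In MDA-MB-231 7 of 8 rose and 0 fell (7 passed adjusted over the list alone, with 0 and 1 in TPM as deposited, 0 and 1 under spike-in scaling), turning under both other scalings. Of fibroblast markers 3 of 5 rose and 0 fell (3 passed adjusted over the list alone, with 1 and 1 in TPM as deposited, 0 and 1 under spike-in scaling) in CAL51, turning under spike-in scaling. In MDA-MB-231 2 of 5 rose and 0 fell (2 passed adjusted over the list alone, with 2 and 1 in TPM as deposited, 1 and 1 under spike-in scaling). Of leukocyte markers 3 of 5 rose and 0 fell (3 passed adjusted over the list alone, with 1 and 0 in TPM as deposited, 0 and 0 under spike-in scaling) in CAL51. In MDA-MB-231 3 of 4 rose and 0 fell (3 passed adjusted over the list alone, with 1 and 0 in TPM as deposited, 0 and 0 under spike-in scaling), and of endothelial markers 0 of 2 rose and 1 fell (1 passed adjusted over the list alone, with 0 and 1 in TPM as deposited, 0 and 1 under spike-in scaling) in CAL51. In MDA-MB-231 0 of 1 rose and 0 fell (0 passed adjusted over the list alone, with 0 and 0 in TPM as deposited, 0 and 1 under spike-in scaling).

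Of small nuclear and nucleolar RNA genes, for which no list was planned or tested, 64 of 166 rose and 2 fell under THZ531 in CAL51 (median 2.03, against 0.12 over all genes), and 34 of 135 rose and 0 fell in MDA-MB-231 (1.26 against 0.13). Of all genes 6760 of 19797 and 7123 of 17181 rose, in MDA-MB-231 a larger share than of small RNA genes, and small RNA genes rising and falling were 58 and 2 in CAL51 and 38 and 4 in MDA-MB-231 with TPM as deposited, and 56 and 5 and 40 and 12 with spike-in scaling. A shift of fragment length that inflates short genes was argued against in CAL51 only, since other genes with 60 to 350 exonic bases had medians of 0.50 and 0.57, 0.248 and 0.451 of the small RNA median (95% of resamplings from 0.198 to 0.383 and 0.339 to 0.778), and 250 of 865 and 189 of 500 of them rose, in MDA-MB-231 a larger share than of small RNA genes. Carryover of total RNA through poly(A) selection may account for part of it, since the most rRNA-rich MDA-MB-231 DMSO library held 2.63 times the share of the lowest THZ531 library. Of the 26 genes that rose in both lines, 16 lay below 50% of their lowest THZ531 library in all 3 rRNA-rich libraries. That DMSO library was in the reference that chose the 26 genes, and the rRNA-rich gefitinib libraries entered the shared estimate of spread. Both favoured genes low in them, so the 16 do not stand for small RNA genes at large and cannot decide on carryover. A failure to end or process these transcripts stays open as an untested hypothesis, which read coverage past their annotated ends would test.

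The interaction gave 2607 genes in MDA-MB-231 and 0 in CAL51. Fewer gefitinib libraries did not end the MDA-MB-231 calls, as 1679 passed without gefitinib replicate 2. Its rRNA-rich libraries were argued against as their whole cause, as 1972 passed without them. Neither test changed CAL51, so neither can tell why it gave 0. Simulated log2 interactions of 1 were recovered in 50% of genes in CAL51 and 76.8% in MDA-MB-231, and library weights gave 960 in CAL51. A library factor shifts all genes alike. With spike-in scaling 99.5% of the tested genes above the sum and 100% of those below it kept their direction. This cannot decide whether scaling was the whole source of the fold changes. Spike-in scaling moved the median of all genes only from 0.07 to -0.15. The genes had been called with medians of 0.64 (SE 0.15) and -0.70 (SE 0.14) with TMM, so few could turn. With spike-ins their medians were 0.37 (SE 0.54) and -0.90 (SE 0.56) (median SE in parentheses). How many genes pass cannot be told apart from an effect of scaling, as calls ended with a larger SE, the count being 4 with TPM as deposited, 8 with spike-in scaling and 1289 with TPM as deposited without the rRNA-rich libraries. Regroupings left chance undecided, as 8 of 100 over the 12 libraries gave as many genes, the real one included (highest other 6942), with the THZ531 effect mixed into the interaction, and 11 of 100 that kept the THZ531 levels did (highest other 4157), all among the 17 that kept the THZ531 libraries apart from the combination libraries, the highest of the rest being 7. A dependence of the THZ531 response on EGFR activity stays open as an untested hypothesis, which the same design with more separate cultures would test.

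Repair genes fell under THZ531 in both lines. Their median span of 62286 bases exceeds that of tested protein-coding genes, 30420 in CAL51 and 31102 in MDA-MB-231. Matched lists were drawn from protein-coding genes. Gene length bias was argued against as the whole cause in CAL51, where the list median of -0.80 lay at percentile 0 of 10000 lists matched on span and level (median -0.22, 95% of them from -0.49 to 0.07). In MDA-MB-231 the list median of -0.43 lay at percentile 24.9 of the matched lists (median -0.30, from -0.70 to 0.09), so length and level may account for it there. Under the combination the percentiles were 0.23 and 20.6. A dependence of repair genes on CDK12 or CDK13 beyond their length stays open as an untested hypothesis for CAL51, which loss of each kinase alone would test.

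Refits of each pair of groups with 3 libraries each over the 10 splits of their 6 libraries are too few for a share under 0.05. In CAL51 the real splits gave for THZ531 10847 (highest other 0, 1 as large), for the combination 12721 (highest other 3, 1 as large) and for the combination against THZ531 4 (highest other 5, 4 as large), the number as large including the real split. In MDA-MB-231 they gave for gefitinib 1 (highest other 5, 8 as large), for THZ531 12528 (highest other 1, 1 as large), for the combination 12327 (highest other 1, 1 as large), for the combination against THZ531 3860 (highest other 6, 1 as large) and for the combination against gefitinib 12081 (highest other 1, 1 as large).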
